A study of Mus musculus with 12 samples.

How the data were processed

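RNA-seq had been done on total RNA of mouse embryonic fibroblasts (strain C57BL/6J-OG2) on days 5 and 9 of OSKM expression, with an shRNA against luciferase, Ncor1 or Ncor2. The labels give 12 libraries in 6 groups of 2, and the comparisons use all of them. The deposited table has 1 column per library and 1 row per gene, with a mouse Ensembl transcript identifier and a symbol. In each group the column with the number 2 was taken as replicate 2, and the column with no number as replicate 1, since it was the other sample of its group. All 12 columns matched a sample in this way.

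The deposited values are a normalized expression score per gene, made of read numbers rounded to whole numbers. Per the submitters' processing notes, RSEM 1.2.17, Bowtie2 2.2.0 and the mouse build mm10 were used, with no role or order given. The labels do not state the normalization or the annotation release. The values themselves show part of it: 91.667% of ranks hold 1 value in all 12 libraries, and every gene reaches at least 101 in 2 libraries, so that genes below this level appear to have been left out before deposit. The highest values stand in blocks of 10, and 249 of 249 genes that could be placed in at least 2 libraries kept 1 place within the block. The median GC content of these places ran from 44.9% to 56%, and place accounted for 40.1% of the rank variance of GC content. This is what values matched to 1 distribution within 10 classes of genes would give, an inference from the values alone. A value is then a rank within its class, higher and lower genes are held near balance, and the highest values sit on steps (median step 4% and largest step 115.5% between the 34 highest blocks). Replicate values were identical for 40.7% of pairs of genes with a mean over 4000 and for 1.8% of those from 200 to 1000. Totals ran from 10314402 to 10321525 in all libraries, so they do not measure depth. The depth is unknown and no counting interval is given. Replicates correlated with r from 0.989 to 0.991 on the log2 scale, across genes.

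The design had named a count model if the table held counts and limma if it held normalized values, and these values called for the limma branch. The score plus 1 was taken to log2, and genes with at least 10 in at least 2 libraries were kept, which removed none of the 10885 genes. One limma model (version 3.58.1, R 4.3.3) with the 6 groups as levels gave 6 residual degrees of freedom, with moderated variances that follow the mean (prior degrees of freedom 5.34) and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all genes within each of 11 comparisons, with a threshold of 0.05. The comparisons were each knockdown against shLuc on each day, the knockdowns against each other on each day, day 9 against day 5 for each shRNA, and the change of each knockdown's effect between the days as an interaction. A fold is that of the fitted log2 change. The groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined.

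There were 34 gene lists for pathways, cell types and complexes, of which 29 had at least 4 measured genes and were tested with camera in limma, at its preset correlation of 0.01, with adjustment over lists within a comparison. Each camera p is given beside the adjusted p with an estimated correlation, and fry was run as a further alternative. Counts of list members past the threshold are given over all genes and with p-values adjusted over the list alone. Genes were named by a rule: 14 fixed genes, the 6 genes with the largest rise and the 6 with the largest fall that passed, did not overlap between groups and reached the median value of 442 in the higher group, and up to 3 genes with the smallest p from each list that passed. In the other comparisons the rule took Ncor1, Ncor2 and 3 genes per direction. The text names part of these genes.

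The code was tested on data simulated for shNcor2 against shLuc on day 5. Of 50 genes per fold it recovered 42% at 1.25-fold, 86% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 4 false calls among 10885 genes. Shared controls were assessed by 100 simulated draws of unchanged knockdowns against the same control libraries. Whether replicate numbers pair the samples was checked from the deviations of same-numbered libraries: they correlated from -0.12 to 0.15 across 15 pairs of groups, with 2 pairs over 0.1, so that the numbers were not used as pairs.

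Alternatives were median-ratio scaling, quantile normalization of the log2 values, other pseudocounts, no filter or a higher one, no trend in the variance, a fit of only the libraries compared, the replicate number as a block, stricter thresholds, and leaving out each library. A filter at 200, a correction of log2 values for GC content, and leaving out genes with a mean of 4000 or more were added after the data had been seen. Coordinates and GC content come from GENCODE vM21 on mm10, in which 10786 of 10885 transcript identifiers (99.09%) were found. Figures were drawn with matplotlib 3.10.9. With 2 libraries per group, single values were not tested for outliers and other splits of the libraries were not counted. Genes listed at 0 in a whole group were given no fold, and 5 lists with under 4 measured genes were not tested.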

Results

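RNA was sequenced from mouse embryonic fibroblasts that carried the reprogramming factors Oct4, Sox2, Klf4 and c-Myc (OSKM, encoded by Pou5f1, Sox2, Klf4 and Myc) on lentiviral vectors. The cells also carried a short hairpin RNA against luciferase (shLuc, the control), against Ncor1 (shNcor1) or against Ncor2 (shNcor2). Ncor1 encodes NCoR and Ncor2 encodes SMRT, corepressor proteins that recruit a histone deacetylase to chromatin. Cells were taken on days 5 and 9, which gave 6 groups of 2 libraries each. The deposited table held normalized values of 10885 genes in 12 libraries. Its totals were fixed by the normalization, so that the sequencing depth is unknown. Values are given as means ± SD of n = 2 libraries in these normalized units, and folds and log2 changes (± SE) come from the fitted model. The labels do not say whether the 2 libraries of a group were separate cultures, so p-values measure the spread between these samples. The highest values stood on coarse steps, on which libraries often share 1 value. These stepped values limit what can be said of highly expressed genes such as Pou5f1, Klf4, Sox2, Myc, Col1a1, Acta2 and Myh9. The table does not separate reads of the vectors from those of the endogenous genes of the 4 factors. The normalization holds higher and lower genes near balance, and which direction held more genes turned with another scaling in several comparisons, so that these splits give no direction of the whole.

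Ncor1 mRNA was lower in both shNcor1 groups and Ncor2 mRNA in both shNcor2 groups, in each of their libraries. On day 5, Ncor1 stood at 3850 and 4220 in the shLuc libraries, at 2928 and 2720 with shNcor1 and at 4007 and 3646 with shNcor2. On day 9 it stood at 3706 and 3646 with shLuc, at 2432 and 2562 with shNcor1 and at 3536 in both shNcor2 libraries. Ncor2 on day 5 stood at 3272 and 3528 with shLuc, at 3314 and 3356 with shNcor1 and at 1776 and 1916 with shNcor2. Its day 9 values were 2582 and 2506 with shLuc, 2480 in both shNcor1 libraries, and 1675 and 1576 with shNcor2. Under its own hairpin Ncor1 kept 70.0% of its shLuc level on day 5 (log2 -0.51 ± 0.06 SE, adjusted p = 0.000989) and 67.9% on day 9 (log2 -0.56 ± 0.06 SE, adjusted p = 0.000574). Ncor2 kept 54.3% on day 5 (log2 -0.88 ± 0.05 SE, adjusted p = 5.39e-07) and 63.9% on day 9 (log2 -0.65 ± 0.05 SE, adjusted p = 1.87e-05). The corepressor that was not targeted stood at 94.8% to 98.1% of shLuc and passed the threshold in 0 of 4 tests (adjusted p from 0.321 to 0.831). With the fit restricted to the 4 libraries compared, the day 5 call of Ncor1 ended (adjusted p = 0.0731). In mm10, Ncor1 (ENSMUST00000018645) lies on chromosome 11 from 62316426 to 62458541. Ncor2 (ENSMUST00000125053) lies on chromosome 5 from 125017153 to 125179219.

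**Figure D1:**
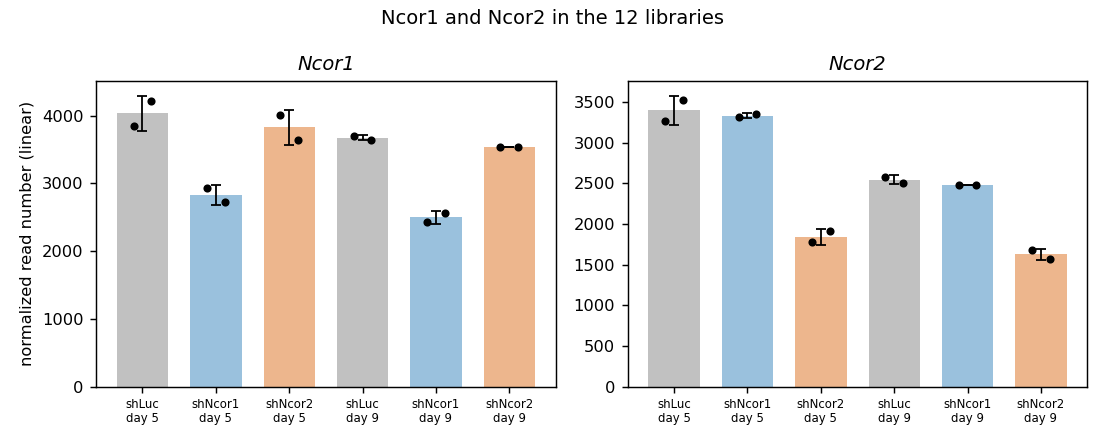
Normalized values of Ncor1 and Ncor2 in the 6 groups, with bars for means, error bars for SD and dots for the 2 libraries of each group. Ncor1 is lowest with shNcor1 (2824 and 2497 on days 5 and 9) and Ncor2 with shNcor2 (1846 and 1626).

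The comparison of day 9 with day 5 under shLuc shows the course of reprogramming in control cells. All 22 measured epithelial genes rose. Epcam, an epithelial adhesion molecule, went from 84 ± 14.1 to 1121 ± 9.9 (13.3-fold higher, log2 3.73 ± 0.15 SE, adjusted p = 1.01e-08), and E-cadherin (Cdh1) from 221 ± 1.4 to 631 ± 12.7 (2.85-fold). Markers of stratified epithelium rose as well, such as Col17a1 from 34 ± 0 to 1226 ± 23.3. Pluripotency genes also rose: Nanog went from 31 ± 7.1 to 217 ± 24.7 (6.86-fold, log2 2.78 ± 0.21 SE, adjusted p = 7.12e-07). Alpl, which encodes the alkaline phosphatase used to stain reprogrammed colonies, went from 75 ± 7.1 to 483 ± 1.4. Ncor2 fell from 3400 ± 181 to 2544 ± 53.7 (log2 -0.42 ± 0.05 SE, adjusted p = 2.78e-05). Ncor1 stood at 3676 ± 42.4 against 4035 ± 262 (adjusted p = 0.0627), and passed without shLuc day 5 replicate 1 (adjusted p = 0.0229).

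In the epithelial list, 22 of 22 measured were higher, 0 lower and 0 not past the threshold (22 and 0 adjusted over the list alone). The epithelial list had a median log2 of 2.49 (camera adjusted p = 1.2e-11, adjusted p = 0.0769 with an estimated correlation). Krt7 went from 7 ± 1.4 to 412 ± 11.3 and Spint2 from 317 ± 15.6 to 1156 ± 0. Of keratinocyte markers, 12 of 13 measured were higher, 0 lower and 1 not past the threshold (12 and 0 adjusted over the list alone). The keratinocyte list had a median log2 of 2.58 (camera adjusted p = 2.33e-07, adjusted p = 0.141 with an estimated correlation). Krt17 went from 20.5 ± 6.4 to 1223 ± 168, though reads shared among keratin paralogs leave the level of single keratins uncertain. Sprr1a, a cornified envelope protein, went from 29.5 ± 17.7 to 606 ± 20.5. Among early pluripotency genes, 12 of 17 measured were higher, 2 lower and 3 not past the threshold (12 and 2 adjusted over the list alone). The early pluripotency list had a median log2 of 0.76 (camera adjusted p = 0.0068, adjusted p = 0.24 with an estimated correlation). Tet2, which oxidizes 5-methylcytosine, rose 1.95-fold, and Trim28, a corepressor of retroviral elements, fell 1.57-fold. Of late pluripotency genes, 6 of 7 measured (24 in the list) were higher, 1 lower and 0 not past the threshold (6 and 1 adjusted over the list alone). The late pluripotency list had a median log2 of 1.30 (camera adjusted p = 0.0152, adjusted p = 0.253 with an estimated correlation). L1td1 was 2.46-fold higher (stepped on day 9) and Tfcp2l1 2.92-fold higher.

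Other lists were tested between the days in shLuc. In the glycolysis list, 10 of 17 measured were higher, 2 lower and 5 not past the threshold (10 and 2 adjusted over the list alone). The glycolysis list had a median log2 of 0.21 (camera adjusted p = 0.0068, adjusted p = 0.24 with an estimated correlation). The glucose transporters Slc2a1 and Slc2a3 went from 1512 ± 40.3 to 5772 ± 161 and from 528 ± 22.6 to 2092 ± 64.3. Among MYC targets and ribosome biogenesis genes, 2 of 28 measured were higher, 19 lower and 7 not past the threshold (2 and 20 adjusted over the list alone). The MYC target list had a median log2 of -0.26 (camera adjusted p = 0.00213, adjusted p = 0.405 with an estimated correlation). Cad, an enzyme of pyrimidine synthesis, went from 5103 ± 114 to 2239 ± 27.6, and the transferrin receptor Tfrc from 2869 ± 133 to 1172 ± 64.3. Myc itself stood higher (12025 ± 1916 to 17120 ± 0, adjusted p = 0.000424, stepped values). Of retinoid and thyroid receptor targets, 6 of 8 measured were higher, 1 lower and 1 not past the threshold (7 and 1 adjusted over the list alone). The retinoid and thyroid list had a median log2 of 0.50 (camera adjusted p = 0.0182, adjusted p = 0.24 with an estimated correlation). The mesenchymal regulators were not called as a list: 2 of 16 measured were higher, 9 lower and 5 not past the threshold (2 and 10 adjusted over the list alone). The mesenchymal regulator list had a median log2 of -0.24 (camera adjusted p = 0.105, adjusted p = 0.53 with an estimated correlation). N-cadherin (Cdh2) fell 2.9-fold and Twist2 2.63-fold. The fibroblast surface marker Thy1 rose from 293 ± 37.5 to 490 ± 19.8 and Cdkn2a from 1196 ± 8.5 to 1933 ± 242.

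In all, 6846 of 10885 genes differed between the days in shLuc at an adjusted p under 0.05. On day 9, 3153 were higher and 3693 lower, and 737 changed at least 2-fold (488 higher, 249 lower). Large rises were those of Klk1 (6 ± 1.4 to 1411 ± 37.5, a member of a family of close paralogs), Trh (20 ± 5.7 to 1575 ± 129) and Krt6a (34.5 ± 4.9 to 1822 ± 179). Grb14 (556 ± 39.6 to 132 ± 5.7), the neuronal tubulin Tubb3 (638 ± 17 to 166 ± 5.7) and the matrix protein Fbn2 (11451 ± 1090.4 to 3097 ± 192) were among the largest falls. Pou5f1 (26169), Klf4 (19774) and Col1a1 (11429) held 1 stepped value in all 4 shLuc libraries, and Sox2 stood at 10375 ± 443 against 10062 ± 0. After the GC correction Pou5f1 (adjusted p = 0.018) and Klf4 (adjusted p = 0.0146) passed as higher. The first principal component, which parts the days, held 74% of the variance over all 12 libraries, and the second held 9.1%.

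**Figure D2:**
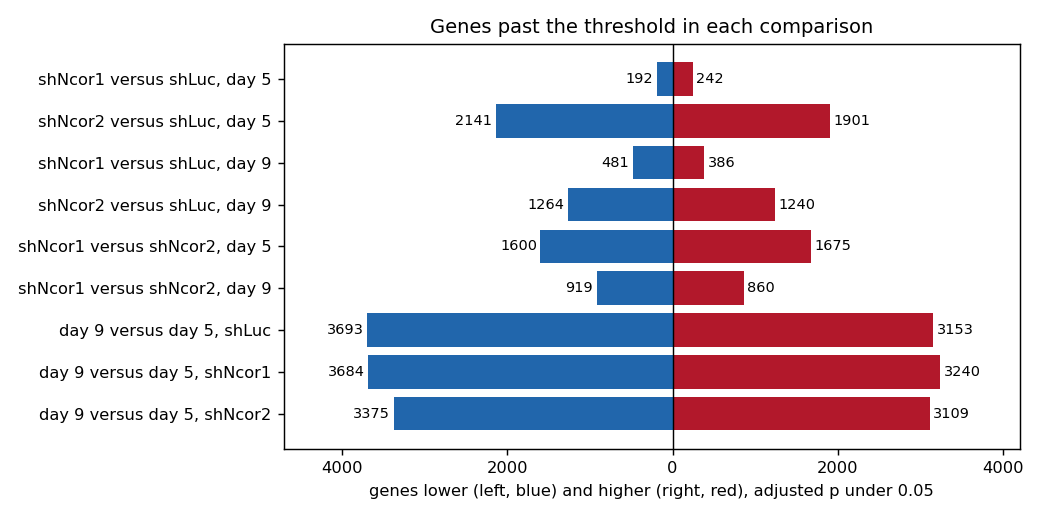
Numbers of genes higher (right, red) and lower (left, blue) at an adjusted p under 0.05 in 9 comparisons. The changes between days (6484 to 6924 genes) exceed those of the knockdowns (434 to 4042 genes).

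On day 5, shNcor1 was compared with shLuc to ask what a lower NCoR level changes early in reprogramming. Of contractile and TGF-beta-responsive genes 6 of 16 rose, among them Tagln (transgelin) from 1506 ± 37.5 to 2192 ± 137 (1.45-fold, log2 0.54 ± 0.09 SE, adjusted p = 0.00779). Il1rn, the interleukin 1 receptor antagonist, rose from 569 ± 4.9 to 950 ± 19.8 (log2 0.74 ± 0.10 SE, adjusted p = 0.00204). Of glycolysis genes 7 of 17 fell, such as Slc2a1 from 1512 ± 40.3 to 1135 ± 41 (log2 -0.41 ± 0.07 SE, adjusted p = 0.00916). Rrm2, a subunit of ribonucleotide reductase, fell from 2640 ± 90.5 to 1969 ± 36.8 (log2 -0.42 ± 0.05 SE, adjusted p = 0.000989). Cdh1 also fell, from 221 ± 1.4 to 159 ± 1.4, as did the epithelial transcription factor Elf3, from 48 ± 2.8 to 18.5 ± 0.7.

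Of TGF-beta targets and contractile genes, 6 of 16 measured were higher, 0 lower and 10 not past the threshold (12 and 0 adjusted over the list alone). The TGF-beta and contractile list had a median log2 of 0.30 (camera adjusted p = 7.59e-09, adjusted p = 0.223 with an estimated correlation). In the glycolysis list, 1 of 17 measured were higher, 7 lower and 9 not past the threshold (1 and 8 adjusted over the list alone). Camera on the glycolysis list gave adjusted p = 4.15e-05 (adjusted p = 0.223 with an estimated correlation) at a median log2 of -0.10. Of DNA replication genes, 0 of 22 measured were higher, 2 lower and 20 not past the threshold (0 and 6 adjusted over the list alone). The DNA replication list had a median log2 of -0.08 (camera adjusted p = 1.19e-05, adjusted p = 0.339 with an estimated correlation). Among p53 and senescence genes, 4 of 19 measured were higher, 0 lower and 15 not past the threshold (7 and 1 adjusted over the list alone). The p53 list had a median log2 of 0.10 (camera adjusted p = 7.82e-05, adjusted p = 0.339 with an estimated correlation). Trp53inp1 went from 1273 ± 9.2 to 1890 ± 106 and Igfbp3 from 728 ± 28.3 to 999 ± 14.8. Other rises were those of Grem1, a BMP antagonist (1.72-fold), Cyp1b1 (1.53-fold), Myof (1.52-fold) and Myh9 (1.73-fold, stepped values). Pxdn (1.52-fold), Ssbp4 (1.49-fold) and Ubac2 (1.47-fold) fell. Klf4 fell from 19774 ± 0 to 16277 ± 1192 (adjusted p = 0.00796), while Pou5f1 and Sox2 held 1 stepped value in all 4 libraries. Nanog stood at 26.5 ± 6.4 against 31 ± 7.1 and Epcam at 88 ± 8.5 against 84 ± 14.1, neither past the threshold.

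At an adjusted p under 0.05, 434 genes differed between shNcor1 and shLuc on day 5, 242 higher and 192 lower, 9 of them at least 2-fold. The count was 236 and 140 without shLuc replicates 1 and 2, 159 and 100 without shNcor1 replicates 1 and 2, and 11 when only the 4 libraries compared were fitted. Without shLuc replicate 2 or without shNcor1 replicate 2 the calls of Klf4, Tagln and Slc2a1 ended. With only the 4 libraries fitted, the genes described as changed, except Myof, Il1rn, Cyp1b1 and Myh9, had adjusted p from 0.0697 to 0.107.

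With shNcor2 on day 5 the comparison with shLuc asked the same of SMRT, and 16 of 16 TGF-beta-responsive and contractile genes and 17 of 24 matrix genes rose. Smooth muscle actin (Acta2) went from 4564 ± 263 to 12252 ± 0 (2.69-fold, log2 1.43 ± 0.08 SE, adjusted p = 6.32e-07), with the higher values on a step. Lox, which crosslinks collagen, went from 738 ± 22.6 to 1963 ± 58 (2.66-fold, log2 1.41 ± 0.05 SE, adjusted p = 2.61e-08). Mcm3, a part of the replicative helicase, fell from 2120 ± 0 to 1514 ± 70.7 (log2 -0.49 ± 0.05 SE, adjusted p = 2.42e-05), and the mitotic regulator Cdc20 from 2094 ± 28.3 to 1307 ± 26.9. The lactate exporter Slc16a3 fell from 881 ± 44.5 to 119 ± 60.8 (7.86-fold, log2 -2.98 ± 0.24 SE, adjusted p = 4.54e-06). All 4 reprogramming factors were lower, Pou5f1 from 26169 ± 0 to 17120 ± 0 and Myc from 12025 ± 1916 to 8361 ± 357, on stepped values. If such a value is a rank within a class, it would also fall when other genes rise past it. In mm10, Acta2 (ENSMUST00000039631) lies on chromosome 19 from 34241090 to 34255590. Lox (ENSMUST00000025409) lies on chromosome 18 from 52516067 to 52529867, and Slc16a3 (ENSMUST00000070653) on chromosome 11 from 120948480 to 120960868.

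Among TGF-beta targets and contractile genes, 16 of 16 measured were higher, 0 lower and 0 not past the threshold (16 and 0 adjusted over the list alone). Camera on the TGF-beta and contractile list gave adjusted p = 5.33e-15 (adjusted p = 0.0559 with an estimated correlation) at a median log2 of 0.96. Ctgf was 2.29-fold higher. Among fibroblast matrix and surface genes, 17 of 24 measured were higher, 1 lower and 6 not past the threshold (18 and 1 adjusted over the list alone). The fibroblast matrix list had a median log2 of 0.59 (camera adjusted p = 2.25e-09, adjusted p = 0.113 with an estimated correlation). Thy1 went from 293 ± 37.5 to 568 ± 62.2 and biglycan (Bgn) from 1384 ± 63.6 to 3707 ± 85.6. Tenascin C (Tnc) was 2-fold and Col1a1 1.5-fold higher, both on stepped values. Of DNA replication genes, 0 of 22 measured were higher, 21 lower and 1 not past the threshold (0 and 22 adjusted over the list alone). Camera on the DNA replication list gave adjusted p = 1.8e-09 (adjusted p = 0.113 with an estimated correlation) at a median log2 of -0.36. In the G2/M list, 0 of 20 measured were higher, 17 lower and 3 not past the threshold (0 and 17 adjusted over the list alone). The G2/M list had a median log2 of -0.33 (camera adjusted p = 8.46e-07, adjusted p = 0.144 with an estimated correlation). Plk1, a mitotic kinase, went from 1121 ± 24 to 768 ± 2.8. Among MYC targets and ribosome biogenesis genes, 1 of 28 measured were higher, 19 lower and 8 not past the threshold (1 and 20 adjusted over the list alone). Camera on the MYC target list gave adjusted p = 5.61e-06 (adjusted p = 0.16 with an estimated correlation) at a median log2 of -0.22. Fibrillarin (Fbl) went from 4421 ± 75 to 3365 ± 245.

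Of glycolysis genes with shNcor2 on day 5, 0 of 17 measured were higher, 12 lower and 5 not past the threshold (1 and 12 adjusted over the list alone). For the glycolysis list the median log2 was -0.30 (camera adjusted p = 2.84e-06, adjusted p = 0.0559 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, went from 856 ± 18.4 to 272 ± 33.9, Slc2a1 fell 1.93-fold and Tpi1 1.5-fold. In the OSKM list, 0 of 4 measured were higher, 4 lower and 0 not past the threshold (0 and 4 adjusted over the list alone). The OSKM list had a median log2 of -0.56 (camera adjusted p = 2e-04, adjusted p = 0.0559 with an estimated correlation). Klf4 went from 19774 ± 0 to 12796 ± 826 and Sox2 from 10062 ± 0 to 8383 ± 357, on stepped values. Among chromatin modifiers, 0 of 30 measured were higher, 13 lower and 17 not past the threshold (0 and 14 adjusted over the list alone). The chromatin modifier list had a median log2 of -0.14 (camera adjusted p = 2e-04, adjusted p = 0.0559 with an estimated correlation). The maintenance DNA methyltransferase Dnmt1 fell 1.34-fold (stepped with shLuc), its partner Uhrf1 1.42-fold and the histone methyltransferase Ezh2 1.31-fold. Cdh1 fell from 221 ± 1.4 to 177 ± 1.4 and Cdkn2a from 1196 ± 8.5 to 929 ± 28.3. Nanog (34 ± 5.7 against 31 ± 7.1) and Zfp42 (26.5 ± 0.7 against 28 ± 5.7) were not past the threshold. The early pluripotency list was not called, with 2 of 17 measured higher and 8 lower (2 and 9 adjusted over the list alone, median log2 -0.27, camera adjusted p = 0.0626).

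In the NF-kB list with shNcor2 on day 5, 6 of 10 measured were higher, 0 lower and 4 not past the threshold (7 and 0 adjusted over the list alone). The NF-kB list had a median log2 of 0.75 (camera adjusted p = 0.000476, adjusted p = 0.0559 with an estimated correlation). Il1rn went from 569 ± 4.9 to 1557 ± 35.4, cyclooxygenase 2 (Ptgs2) from 1189 ± 119.5 to 2356 ± 187 and the chemokine Ccl2 from 126 ± 8.5 to 265 ± 20.5. Of AP-1 and immediate early genes, 7 of 12 measured were higher, 0 lower and 5 not past the threshold (8 and 0 adjusted over the list alone). The immediate early list had a median log2 of 0.34 (camera adjusted p = 0.00301, adjusted p = 0.138 with an estimated correlation). Jun was 1.36-fold and Ier3 2.09-fold higher. Among PPAR targets and adipocyte genes, 5 of 11 measured were higher, 0 lower and 6 not past the threshold (5 and 0 adjusted over the list alone). The PPAR list had a median log2 of 0.21 (camera adjusted p = 0.0191, adjusted p = 0.113 with an estimated correlation). The lipid droplet protein Plin2 rose 1.96-fold and the peroxisomal oxidase Acox1 1.48-fold. Of markers of primitive endoderm, another cell type, 6 of 7 measured were higher, 0 lower and 1 not past the threshold (6 and 0 adjusted over the list alone). The primitive endoderm list had a median log2 of 0.53 (camera adjusted p = 0.000197, adjusted p = 0.0559 with an estimated correlation). Those that rose included Lama1 (139 ± 3.5 to 247 ± 31.8) and Col4a2 (6526 ± 260.2 to 9426 ± 0, stepped with shNcor2), basement membrane genes that are not specific to that cell type.

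Between shNcor2 and shLuc on day 5, 4042 genes differed at an adjusted p under 0.05, 1901 higher and 2141 lower, and 161 changed at least 2-fold, 133 higher and 28 lower. The split turned to 2151 higher and 1837 lower with median-ratio scaling and to 2138 and 1843 with the GC correction. Replicate 2 of shNcor2 on day 5 stood apart from replicate 1 on the first principal component (-29 against -38.2), by 9.2, where replicates of the other groups differed by at most 1.6. It had 9 genes at 0, against 16 to 26 in the other libraries of day 5. Without it 2838 genes passed, and the lists described here kept their direction and their calls. The largest rises by the rule included Col12a1 (1634 ± 289 to 5999.5 ± 138, 3.7-fold), Fbln5 (2483 ± 126 to 8158 ± 0, stepped with shNcor2), Synpo (142 ± 2.8 to 449.5 ± 4.9), Prss23 (892 ± 26.2 to 2658 ± 153) and Jam2 (301 ± 9.2 to 892 ± 2.8). Besides Slc16a3 and Pdk1, the largest falls included Ccnd3, a D-type cyclin (1519.5 ± 3.5 to 640 ± 28.3), Trip13 (475 ± 26.9 to 202 ± 15.6) and Bnip3, a mitophagy receptor (452 ± 12 to 195 ± 48.1). In simulated data, 86% of genes changed 1.5-fold were recovered, which need not hold here.

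On day 9, 7 of 17 early pluripotency genes were higher and 15 of 24 matrix genes lower in shNcor1 cells than in shLuc cells. Dnmt3b, a de novo DNA methyltransferase, rose from 127 ± 35.4 to 321 ± 9.9 (2.56-fold, log2 1.36 ± 0.15 SE, adjusted p = 0.000773). The apolipoprotein gene Apoe rose from 200 ± 56.6 to 568 ± 19.8 (2.89-fold, log2 1.53 ± 0.20 SE, adjusted p = 0.0018). The collagen-binding proteoglycan lumican (Lum) fell from 169 ± 2.1 to 60.5 ± 16.3 (2.81-fold, log2 -1.49 ± 0.16 SE, adjusted p = 0.000714). Col3a1 fell from 11074 ± 546 to 6710 ± 0 and Col1a1 from 11429 ± 0 to 7537 ± 803, on stepped values. Nanog stood at 360 ± 53.7 against 217 ± 24.7 (adjusted p = 0.0574) and Zfp42 at 101 ± 12 against 56.5 ± 6.4 (adjusted p = 0.0604). Epcam stood at 1528 ± 12 against 1121 ± 9.9 (adjusted p = 0.102) and Cdh1 at 718 ± 42.4 against 631 ± 12.7 (adjusted p = 0.0831). In mm10, Dnmt3b (ENSMUST00000072997) lies on chromosome 2 from 153649450 to 153687730 and Lum (ENSMUST00000038160) on chromosome 10 from 97565128 to 97572703.

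Among early pluripotency genes, 7 of 17 measured were higher, 0 lower and 10 not past the threshold (10 and 0 adjusted over the list alone). Camera on the early pluripotency list gave adjusted p = 8.57e-06 (adjusted p = 0.115 with an estimated correlation) at a median log2 of 0.42. Of fibroblast matrix and surface genes, 1 of 24 measured were higher, 15 lower and 8 not past the threshold (1 and 18 adjusted over the list alone). Camera on the fibroblast matrix list gave adjusted p = 7.29e-12 (adjusted p = 0.135 with an estimated correlation) at a median log2 of -0.34. Thy1 stood at 555 ± 9.2 against 490 ± 19.8 (adjusted p = 0.26). Among MYC targets and ribosome biogenesis genes, 5 of 28 measured were higher, 0 lower and 23 not past the threshold (6 and 0 adjusted over the list alone). For the MYC target list the median log2 was 0.10 (camera adjusted p = 3.99e-05, adjusted p = 0.33 with an estimated correlation). Tfrc went from 1172 ± 64.3 to 1678 ± 40.3. Of LXR and sterol-responsive genes, 1 of 15 measured were higher, 5 lower and 9 not past the threshold (1 and 7 adjusted over the list alone). The LXR and sterol list had a median log2 of -0.08 (camera adjusted p = 0.00617, adjusted p = 0.135 with an estimated correlation). The cholesterol exporter Abca1 fell 1.33-fold, and Apoe was the member that rose. Among retinoid and thyroid receptor targets, 0 of 8 measured were higher, 2 lower and 6 not past the threshold (0 and 4 adjusted over the list alone). Camera on the retinoid and thyroid list gave adjusted p = 0.000921 (adjusted p = 0.115 with an estimated correlation) at a median log2 of -0.26. Crabp2, a retinoic acid-binding protein, went from 1773 ± 100.4 to 1328 ± 36.8. Cmah (5307 ± 834 to 10049 ± 892, stepped values), the histone chaperone Nasp (2161 ± 66.5 to 3565 ± 286), Upp1 (293 ± 1.4 to 472 ± 19.8) and Slc2a3 (2092 ± 64.3 to 3313 ± 159.8) were among the largest rises by the rule. Efnb1 (1272 ± 56.6 to 762 ± 20.5) and Fndc1 (1636 ± 70.7 to 988 ± 110.3) were among the largest falls. Trp53inp1 rose from 2684 ± 94.8 to 3850 ± 0. Pou5f1 and Klf4 held 1 stepped value in all 4 libraries.

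Between shNcor1 and shLuc on day 9, 867 genes differed at an adjusted p under 0.05, 386 higher and 481 lower, 18 of them at least 2-fold. The count was 165 and 444 without shLuc replicates 1 and 2, 475 and 496 without shNcor1 replicates 1 and 2, 90 when only the 4 libraries compared were fitted and 576 with no trend in the variance. With only the 4 libraries, the calls of Lum (adjusted p = 0.0615), Dnmt3b (0.0651) and Crabp2 (0.066) ended and Epcam passed (0.0433). Nanog and Zfp42 passed under some other settings (adjusted p from 0.0253 to 0.047).

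In shNcor2 cells on day 9, 7 of 17 early pluripotency genes and E-cadherin were higher than in shLuc cells, and 1 of the 17 was lower. Gdf3, a TGF-beta family ligand of pluripotent cells, rose from 153 ± 16.3 to 454 ± 28.3 (2.97-fold, log2 1.57 ± 0.16 SE, adjusted p = 0.00011). Dnmt3b rose from 127 ± 35.4 to 384 ± 48.1 (3.05-fold, log2 1.61 ± 0.15 SE, adjusted p = 5.81e-05). The pluripotency marker Zfp42 (Rex1) rose from 56.5 ± 6.4 to 129 ± 13.4 (2.25-fold, log2 1.17 ± 0.24 SE, adjusted p = 0.00568) and Cdh1 from 631 ± 12.7 to 937 ± 13.4 (1.48-fold). Zfp42 reached the listing floor of 101 only in knockdown libraries of day 9, which favors its rise. Of contractile and TGF-beta-responsive genes 9 of 16 were higher, with Acta2 going from 2693 ± 94.8 to 5144 ± 557 and Myl9, a myosin light chain, from 254 ± 0.7 to 615 ± 103. Myc was lower (17120 ± 0 to 10356 ± 444, adjusted p = 0.000313), whereas Pou5f1 and Klf4 held 1 stepped value in all 4 libraries. Nanog (299 ± 4.2 against 217 ± 24.7, adjusted p = 0.13) and Epcam (1437 ± 4.2 against 1121 ± 9.9, adjusted p = 0.118) did not pass. Both passed when only the 4 libraries compared were fitted (adjusted p = 0.0407 and 0.0107).

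Of early pluripotency genes, 7 of 17 measured were higher, 1 lower and 9 not past the threshold (7 and 1 adjusted over the list alone). For the early pluripotency list the median log2 was 0.22 (camera adjusted p = 0.00346, adjusted p = 0.14 with an estimated correlation). Trim28 rose 1.17-fold. Of TGF-beta targets and contractile genes, 9 of 16 measured were higher, 0 lower and 7 not past the threshold (10 and 0 adjusted over the list alone). For the TGF-beta and contractile list the median log2 was 0.28 (camera adjusted p = 3.15e-06, adjusted p = 0.14 with an estimated correlation). Fibroblast matrix and surface genes moved both ways: 10 of 24 measured were higher, 4 lower and 10 not past the threshold (12 and 4 adjusted over the list alone). For the fibroblast matrix list the median log2 was 0.23 (camera adjusted p = 0.00307, adjusted p = 0.333 with an estimated correlation). Thy1 went from 490 ± 19.8 to 917 ± 55.2 and Tnc from 2352 ± 0 to 3490 ± 45.3, and Col1a1 stood at 11123 ± 1535 against 11429 ± 0 (adjusted p = 0.747). In the glycolysis list, 1 of 17 measured were higher, 8 lower and 8 not past the threshold (1 and 10 adjusted over the list alone). The glycolysis list had a median log2 of -0.17 (camera adjusted p = 0.00136, adjusted p = 0.133 with an estimated correlation). Pdk1 went from 2013 ± 97.6 to 1138 ± 105 and Pfkm, the muscle phosphofructokinase, from 856 ± 34.6 to 558 ± 17. Among MYC targets and ribosome biogenesis genes, 10 of 28 measured were higher, 1 lower and 17 not past the threshold (16 and 1 adjusted over the list alone). The MYC target list had a median log2 of 0.16 (camera adjusted p = 0.000208, adjusted p = 0.218 with an estimated correlation). Tfrc went from 1172 ± 64.3 to 2250 ± 192.

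NCoR and SMRT are known to act with nuclear receptors, and of 4 lists built around these receptors, camera called 3 as lower with shNcor2 on day 9, calls that all ended with an estimated correlation (adjusted p = 0.112, 0.112 and 0.218). Of LXR and sterol-responsive genes, 2 of 15 measured were higher, 8 lower and 5 not past the threshold (2 and 10 adjusted over the list alone). Camera on the LXR and sterol list gave adjusted p = 0.00279 (adjusted p = 0.112 with an estimated correlation) at a median log2 of -0.18. Abca1 went from 4346 ± 46 to 2521 ± 149 and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, from 3017 ± 60.8 to 2560 ± 56.6. Among retinoid and thyroid receptor targets, 0 of 8 measured were higher, 4 lower and 4 not past the threshold (0 and 4 adjusted over the list alone). For the retinoid and thyroid list the median log2 was -0.31 (camera adjusted p = 0.00279, adjusted p = 0.112 with an estimated correlation). Transglutaminase 2 (Tgm2) went from 2209 ± 141 to 1278 ± 71.4 and Klf9 from 551 ± 20.5 to 435 ± 35.4. In the circadian and REV-ERB list, 0 of 14 measured were higher, 3 lower and 11 not past the threshold (0 and 3 adjusted over the list alone). The circadian list had a median log2 of -0.20 (camera adjusted p = 0.00921, adjusted p = 0.218 with an estimated correlation). The clock-related genes Per3 and Dbp fell 1.89-fold and 2.19-fold. The PPAR list was not called: 3 of 11 measured were higher, 2 lower and 6 not past the threshold (4 and 2 adjusted over the list alone). Camera on the PPAR list gave adjusted p = 0.0914 (adjusted p = 0.218 with an estimated correlation) at a median log2 of 0.14.

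In the NF-kB list with shNcor2 on day 9, 6 of 10 measured were higher, 0 lower and 4 not past the threshold (6 and 0 adjusted over the list alone). Camera on the NF-kB list gave adjusted p = 0.00279 (adjusted p = 0.112 with an estimated correlation) at a median log2 of 0.39. Vcam1 rose 1.4-fold and Ccl2 1.69-fold. Of markers of keratinocytes, another cell type, 6 of 13 measured were higher, 0 lower and 7 not past the threshold (7 and 0 adjusted over the list alone). Camera on the keratinocyte list gave adjusted p = 0.00346 (adjusted p = 0.218 with an estimated correlation) at a median log2 of 0.49. Sfn went from 474 ± 48.8 to 874 ± 45.3. Of HOX genes, 0 of 12 measured were higher, 6 lower and 6 not past the threshold (0 and 7 adjusted over the list alone). The HOX list had a median log2 of -0.40 (camera adjusted p = 0.00393, adjusted p = 0.112 with an estimated correlation). Hoxc4 went from 133 ± 7.1 to 92 ± 5.7. In the heat shock list, 4 of 12 measured were higher, 0 lower and 8 not past the threshold (6 and 0 adjusted over the list alone). The heat shock list had a median log2 of 0.16 (camera adjusted p = 0.00216, adjusted p = 0.147 with an estimated correlation). The chaperone gene Hsph1 rose 1.64-fold. Cdkn2a fell from 1933 ± 242 to 1428 ± 25.5.

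Between shNcor2 and shLuc on day 9, 2504 genes differed at an adjusted p under 0.05, 1240 higher and 1264 lower, and 70 changed at least 2-fold, 40 higher and 30 lower. The largest rise by the rule was that of Akr1c18 (256 ± 31.1 to 1436 ± 161, 5.59-fold). Akr1c18 and Myh2 (212 ± 21.2 to 585 ± 63.6) belong to families of close paralogs, which leaves the source of their reads uncertain. Clec3b rose 2.01-fold, while Eya2 (479.5 ± 37.5 to 216 ± 32.5), Pdzd7 (723 ± 4.9 to 328 ± 24.7) and Ccnd3 (1572 ± 52.3 to 714 ± 36.8) were among the largest falls. The count was 1172 without shLuc replicate 1, 1308 without shNcor2 replicate 2 and 1501 when only the 4 libraries compared were fitted.

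**Figure D3:**
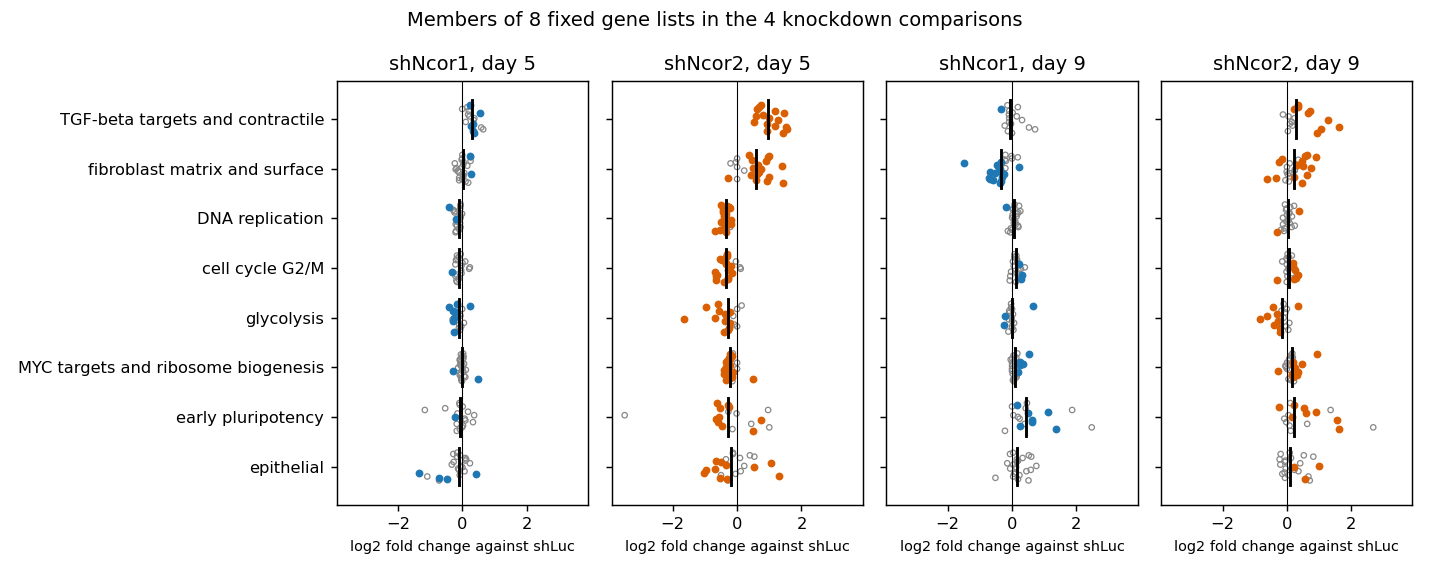
Log2 fold change of each measured member of 8 gene lists in the 4 comparisons of a knockdown with shLuc, with filled points for an adjusted p under 0.05 and black lines for medians. The TGF-beta and contractile list lies highest with shNcor2 on day 5 (median 0.96), and early pluripotency lies above 0 in both knockdowns on day 9 (medians 0.42 and 0.22).

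**Figure D4:**
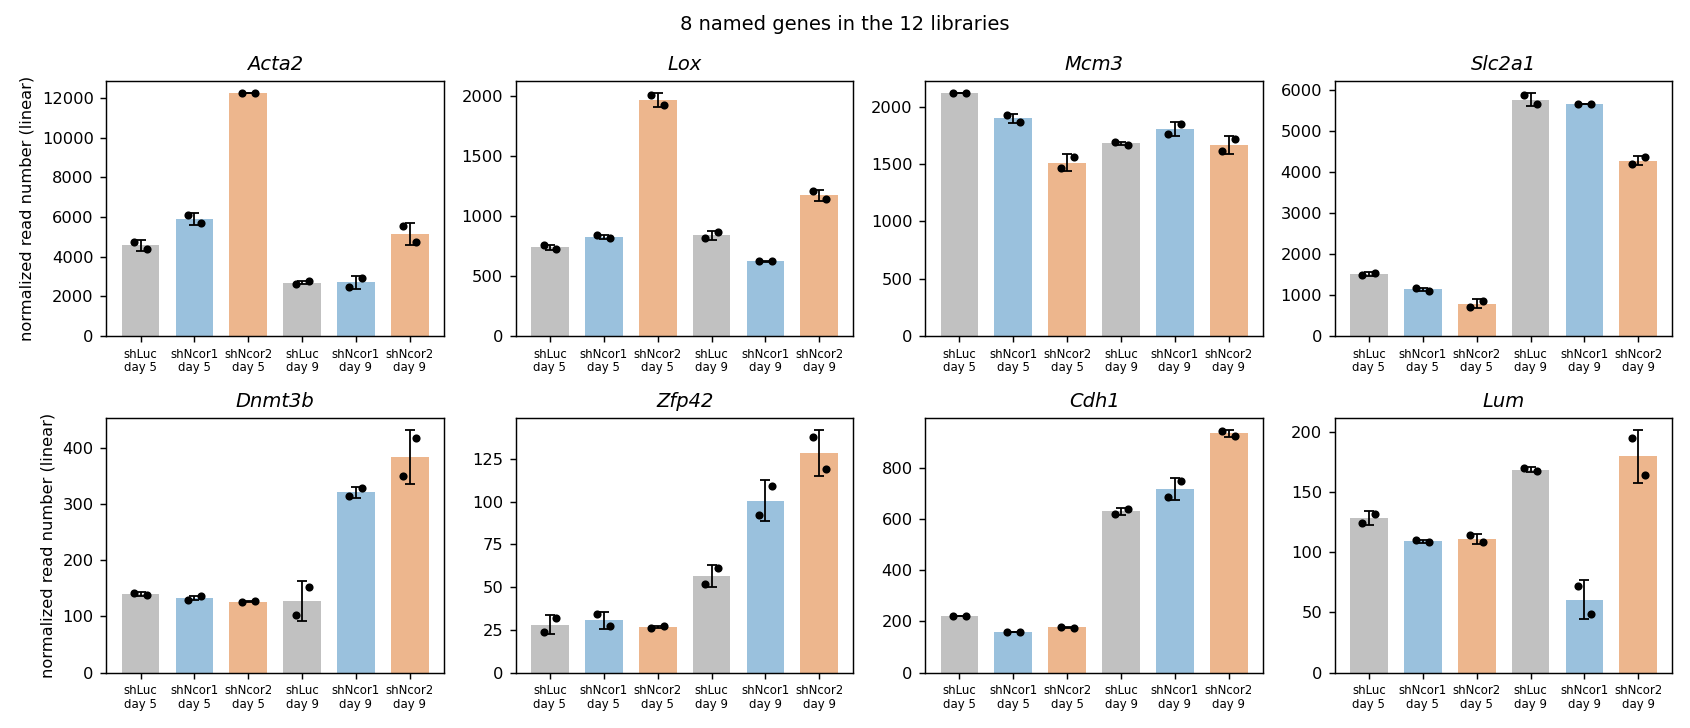
Normalized values per library of 8 genes in the 6 groups. Acta2 and Lox are highest with shNcor2 on day 5 (12252 and 1963), Mcm3 and Slc2a1 are lower there than with shLuc, and Dnmt3b and Zfp42 are higher with shNcor2 than with shLuc on day 9.

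The knockdowns were also compared directly with each other. On day 5, Col12a1 was lower with shNcor1 than with shNcor2 (1719.5 ± 152 against 5999.5 ± 138, 3.49-fold, log2 -1.80 ± 0.11 SE, adjusted p = 1.07e-06), as were Fbln5 (2859 ± 109.6 against 8158 ± 0) and Synpo (137 ± 6.4 against 449.5 ± 4.9). Slc16a3 (463 ± 43.8 against 119 ± 60.8), Pdk1 (698 ± 55.9 against 272 ± 33.9) and the ETS factor Etv4 (539 ± 4.2 against 240 ± 14.1) were higher with shNcor1. Of TGF-beta targets and contractile genes, 0 of 16 measured were higher, 16 lower and 0 not past the threshold (0 and 16 adjusted over the list alone). The TGF-beta and contractile list had a median log2 of -0.61 (camera adjusted p = 2.72e-13, adjusted p = 0.086 with an estimated correlation). Among fibroblast matrix and surface genes, 0 of 24 measured were higher, 18 lower and 6 not past the threshold (1 and 18 adjusted over the list alone). The fibroblast matrix list had a median log2 of -0.60 (camera adjusted p = 1.06e-10, adjusted p = 0.117 with an estimated correlation). Of MYC targets, 16 of 28 measured were higher, 0 lower and 12 not past the threshold (22 and 0 adjusted over the list alone). Camera on the MYC target list gave adjusted p = 6.62e-07 (adjusted p = 0.172 with an estimated correlation) at a median log2 of 0.20. Of DNA replication genes, 14 of 22 measured were higher, 1 lower and 7 not past the threshold (14 and 1 adjusted over the list alone). For the DNA replication list the median log2 was 0.23 (camera adjusted p = 9.55e-06, adjusted p = 0.226 with an estimated correlation). Of the OSKM genes, 4 of 4 measured were higher, 0 lower and 0 not past the threshold (4 and 0 adjusted over the list alone). Camera on the OSKM list gave adjusted p = 0.000253 (adjusted p = 0.086 with an estimated correlation) at a median log2 of 0.37. Of primitive endoderm markers, 0 of 7 measured were higher, 5 lower and 2 not past the threshold (0 and 6 adjusted over the list alone). Camera on the primitive endoderm list gave adjusted p = 0.000253 (adjusted p = 0.086 with an estimated correlation) at a median log2 of -0.49. Of keratinocyte markers, 1 of 13 measured were higher, 6 lower and 6 not past the threshold (1 and 6 adjusted over the list alone). For the keratinocyte list the median log2 was -0.47 (camera adjusted p = 0.0107, adjusted p = 0.226 with an estimated correlation). This call also ended with quantile normalization (0.0501).

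In all, 3275 genes differed between the knockdowns on day 5, 1675 higher and 1600 lower with shNcor1, and 108 differed at least 2-fold, 15 higher and 93 lower. The split turned to 1444 higher and 1822 lower with median-ratio scaling and to 1445 and 1842 with the GC correction. The count was 2053 and 1948 without shNcor1 replicates 1 and 2, and 1969 and 2149 without shNcor2 replicates 1 and 2. Ncor1 and Ncor2 differed in the directions of their hairpins (log2 -0.44 ± 0.06 SE and log2 0.85 ± 0.05 SE).

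Of matrix genes with shNcor1 against shNcor2 on day 9, 2 of 24 measured were higher, 20 lower and 2 not past the threshold (2 and 20 adjusted over the list alone). Camera on the fibroblast matrix list gave adjusted p = 5.27e-16 (adjusted p = 0.113 with an estimated correlation) at a median log2 of -0.60. Among TGF-beta targets and contractile genes, 0 of 16 measured were higher, 8 lower and 8 not past the threshold (0 and 11 adjusted over the list alone). Camera on the TGF-beta and contractile list gave adjusted p = 5.12e-08 (adjusted p = 0.118 with an estimated correlation) at a median log2 of -0.37. Of glycolysis genes, 7 of 17 measured were higher, 0 lower and 10 not past the threshold (7 and 0 adjusted over the list alone). Camera on the glycolysis list gave adjusted p = 0.000115 (adjusted p = 0.113 with an estimated correlation) at a median log2 of 0.11. Among early pluripotency genes, 3 of 17 measured were higher, 2 lower and 12 not past the threshold (3 and 2 adjusted over the list alone). The early pluripotency list had a median log2 of 0 (camera adjusted p = 0.763, adjusted p = 0.836 with an estimated correlation). Of markers of other cell types, 0 of 7 primitive endoderm genes were higher and 4 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.113 with an estimated correlation). Of 13 keratinocyte genes, 1 was higher and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.00884, adjusted p = 0.279 with an estimated correlation), a call that ended without shNcor1 day 9 replicate 1 (0.0792). Akr1c18 (296 ± 0 against 1436 ± 161) and Sostdc1, a BMP antagonist (181 ± 32.5 against 498 ± 8.5), were lower with shNcor1. Nqo1, an NRF2-responsive quinone reductase (682 ± 22.6 against 334 ± 2.8), and Pdzd7 (632 ± 76.4 against 328 ± 24.7) were higher. Ncor1 (log2 -0.50 ± 0.06 SE) and Ncor2 (log2 0.61 ± 0.05 SE) again differed by hairpin. There were 1779 genes past the threshold, 860 higher and 919 lower, and 55 differed at least 2-fold, 16 higher and 39 lower. The count was 1099 without shNcor1 replicate 1, 1023 and 949 without shNcor2 replicates 1 and 2, and 532 when only the 4 libraries compared were fitted.

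Whether a knockdown acted differently on the 2 days was tested as an interaction. Of the shNcor2 effects on DNA replication genes, on day 9 against day 5, 19 of 22 measured were higher, 0 lower and 3 not past the threshold (20 and 0 adjusted over the list alone). The DNA replication list had a median log2 of 0.40 (camera adjusted p = 1.82e-09, adjusted p = 0.135 with an estimated correlation). In the G2/M list, 17 of 20 measured were higher, 0 lower and 3 not past the threshold (17 and 0 adjusted over the list alone). Camera on the G2/M list gave adjusted p = 2.2e-08 (adjusted p = 0.135 with an estimated correlation) at a median log2 of 0.44. Of MYC targets and ribosome biogenesis genes, 21 of 28 measured were higher, 1 lower and 6 not past the threshold (24 and 1 adjusted over the list alone). For the MYC target list the median log2 was 0.37 (camera adjusted p = 8.52e-10, adjusted p = 0.128 with an estimated correlation). Of TGF-beta targets and contractile genes, 0 of 16 measured were higher, 12 lower and 4 not past the threshold (0 and 12 adjusted over the list alone). For the TGF-beta and contractile list the median log2 was -0.49 (camera adjusted p = 2.07e-08, adjusted p = 0.128 with an estimated correlation). Among fibroblast matrix and surface genes, 1 of 24 measured were higher, 12 lower and 11 not past the threshold (2 and 14 adjusted over the list alone). For the fibroblast matrix list the median log2 was -0.39 (camera adjusted p = 1.81e-05, adjusted p = 0.17 with an estimated correlation). Of early pluripotency genes, 10 of 17 measured were higher, 0 lower and 7 not past the threshold (11 and 1 adjusted over the list alone). Camera on the early pluripotency list gave adjusted p = 0.000103 (adjusted p = 0.128 with an estimated correlation) at a median log2 of 0.61. The shNcor2 effect on this list had a median of -0.27 on day 5 and 0.22 on day 9.

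Of the genes taken by the naming rule, the shNcor2 effect differed between the days for Slc16a3 (log2 2.35 ± 0.34 SE, adjusted p = 0.000748), Krt5 (log2 1.49 ± 0.30 SE, adjusted p = 0.00512), Galnt2 (log2 -1.42 ± 0.30 SE, adjusted p = 0.00687) and Rock2 (log2 -1.32 ± 0.14 SE, adjusted p = 0.000186). In all, 2635 genes passed, 1371 with a higher and 1264 with a lower effect on day 9, 111 of them by at least 2-fold, and 1742 passed without shLuc day 5 replicate 1. The knockdown of Ncor2 itself was weaker on day 9 (log2 0.23 ± 0.07 SE, adjusted p = 0.0352). This call ended without shLuc day 5 replicate 2 (adjusted p = 0.116), shLuc day 9 replicate 1 or 2 (0.0578 and 0.0958), shNcor2 day 5 replicate 1 (0.129) or shNcor2 day 9 replicate 1 (0.113). It also ended with median-ratio scaling (0.0542), no trend in the variance (0.0785) or only the 8 libraries of shLuc and shNcor2 (0.0589).

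For the change of the shNcor1 effect, no list call held with an estimated correlation. Among fibroblast matrix and surface genes, 1 of 24 measured were higher, 9 lower and 14 not past the threshold (1 and 16 adjusted over the list alone). The fibroblast matrix list had a median log2 of -0.41 (camera adjusted p = 1.26e-13, adjusted p = 0.117 with an estimated correlation). Of TGF-beta targets and contractile genes, 0 of 16 measured were higher, 4 lower and 12 not past the threshold (0 and 8 adjusted over the list alone). The TGF-beta and contractile list had a median log2 of -0.32 (camera adjusted p = 2.91e-07, adjusted p = 0.117 with an estimated correlation). Among early pluripotency genes, 3 of 17 measured were higher, 0 lower and 14 not past the threshold (6 and 0 adjusted over the list alone). For the early pluripotency list the median log2 was 0.53 (camera adjusted p = 6.61e-07, adjusted p = 0.117 with an estimated correlation). In the G2/M list, 1 of 20 measured were higher, 0 lower and 19 not past the threshold (10 and 0 adjusted over the list alone). For the G2/M list the median log2 was 0.21 (camera adjusted p = 5.95e-08, adjusted p = 0.117 with an estimated correlation). Of DNA replication genes, 0 of 22 measured were higher, 0 lower and 22 not past the threshold (8 and 0 adjusted over the list alone). Camera on the DNA replication list gave adjusted p = 5.38e-08 (adjusted p = 0.117 with an estimated correlation) at a median log2 of 0.19. Of 13 keratinocyte markers, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 0.3, camera adjusted p = 0.0451, adjusted p = 0.286 with an estimated correlation). This call ended in several fits with 1 library left out and with quantile normalization (0.121). Of 7 primitive endoderm markers, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, median log2 -0.28, camera adjusted p = 0.0207, adjusted p = 0.117 with an estimated correlation), a call that ended without shNcor1 day 5 replicate 1 (0.0662). Ndrg1 had a higher effect on day 9 (log2 0.89 ± 0.11 SE, adjusted p = 0.00628) and Myh9 a lower one (log2 -0.83 ± 0.07 SE, adjusted p = 0.000396, stepped values). The change for Ncor1 itself was log2 -0.04 ± 0.08 SE, adjusted p = 0.848.

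Here 123 genes passed, 55 with a higher and 68 with a lower shNcor1 effect on day 9, 7 of them by at least 2-fold. The count was 33 and 63 without shLuc day 5 replicates 1 and 2, 28 and 60 without shLuc day 9 replicates 1 and 2, 29 and 22 without shNcor1 day 5 replicates 1 and 2, and 48 without shNcor1 day 9 replicate 2. It was 18 when only the 8 libraries of shLuc and shNcor1 were fitted and 30 with no trend in the variance.

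The genes called in both knockdowns mostly moved the same way. On day 5, 196 genes were higher in both and 106 lower in both, where independent calls would give 42.3 and 37.8, and 26 of the 328 genes called in both went in opposite directions. On day 9, 239 were higher and 212 lower in both (44 and 55.9 for independent calls), and 38 of 489 were opposite. Both knockdowns were compared with the same shLuc libraries, which makes changes alike. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.493 on day 5 and 0.499 on day 9. Simulated knockdowns with no effect against shared controls gave means of 0.5 and 0.49. The covariance was 0.0417 on day 5 and 0.032 on day 9, above the highest of 100 simulated draws (0.0148 and 0.018), in which genes varied independently. In those draws at most 2 genes per direction were called in both. Unchanged knockdowns yield almost no calls, so this number does not show how many shared calls come from the shared controls. Part of the overlap can still come from the shared controls, as splitting them would leave 1 library for each knockdown.

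Between the days, which have separate controls, shNcor1 shared 39 higher and 65 lower genes (8.6 and 8.5 for independent calls), with 6 of 110 opposite. For shNcor2, 478 higher and 466 lower genes were shared (216.6 and 248.6), and 309 of 1253 went in opposite directions on the 2 days.

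Within each knockdown, day 9 was also compared with day 5. With shNcor1, 6924 genes differed between the days (3240 higher, 3684 lower, 826 at least 2-fold, of which 496 higher) and with shNcor2, 6484 (3109 higher, 3375 lower, 731 at least 2-fold, of which 436 higher). In the epithelial list with shNcor1, 21 of 22 measured were higher, 0 lower and 1 not past the threshold (21 and 0 adjusted over the list alone). Camera on the epithelial list gave adjusted p = 6.93e-12 (adjusted p = 0.0731 with an estimated correlation) at a median log2 of 2.91. Among early pluripotency genes with shNcor1, 13 of 17 measured were higher, 1 lower and 3 not past the threshold (13 and 1 adjusted over the list alone). The early pluripotency list had a median log2 of 1.39 (camera adjusted p = 3.31e-05, adjusted p = 0.079 with an estimated correlation). With shNcor2 the same lists rose. In the epithelial list, 22 of 22 measured were higher, 0 lower and 0 not past the threshold (22 and 0 adjusted over the list alone). For the epithelial list the median log2 was 2.70 (camera adjusted p = 8.42e-13, adjusted p = 0.0479 with an estimated correlation). Of early pluripotency genes, 16 of 17 measured were higher, 1 lower and 0 not past the threshold (16 and 1 adjusted over the list alone). Camera on the early pluripotency list gave adjusted p = 2.58e-07 (adjusted p = 0.0479 with an estimated correlation) at a median log2 of 1.74. These 2 list calls with shNcor2 were the only ones, over the 11 comparisons, that held with an estimated correlation. Markers of keratinocytes, another cell type, rose beside these lists: 12 of 13 measured genes were higher and 0 lower in each knockdown (12 and 0 adjusted over the list alone). The medians were 3.05 with shNcor1 (camera adjusted p = 6.1e-08, adjusted p = 0.079 with an estimated correlation) and 3.29 with shNcor2 (1.22e-08 and 0.0648). With shNcor1, 1 of 7 neural markers was higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0552), and 0 of 7 primitive endoderm markers were higher and 4 lower (0 and 4, 0.169). With shNcor2 the numbers were 1 and 5 (1 and 6, 0.0235, 0.121 with an estimated correlation) and 0 and 4 (0 and 5, 0.0175, 0.121). Krt17 with shNcor1 (12.5 ± 0.7 to 1318 ± 185) and Krt5 with shNcor2 (7 ± 1.4 to 663 ± 74.2) were among the largest rises, with reads shared among keratin paralogs. S100a14 went from 5.5 ± 4.9 to 463 ± 27.6 with shNcor2. Grb14 fell in both (681 ± 40.3 to 141 ± 0 and 884 ± 57.3 to 227 ± 12). Tubb3 fell with shNcor1 (749.5 ± 10.6 to 185 ± 4.2), and Dusp1 (710 ± 125 to 204 ± 37.5) and Ptgs2 (2356 ± 187 to 691 ± 72.8) fell with shNcor2. Ncor2 fell with shNcor1 as well (3335 ± 29.7 to 2480 ± 0).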

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

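The test of the interaction was planned for all genes, while the test of a deviating library and that of the reprogramming factors were chosen only after the results were seen. The shNcor2 effect differed between day 5 and day 9 for 2635 genes (1742 without shLuc day 5 replicate 1) at an adjusted p under 0.05. Of the genes named by the rule, the log2 effect of shNcor2 was higher on day 9 by 2.35 for Slc16a3 and 1.49 for Krt5, and its change was -1.42 for Galnt2 and -1.32 for Rock2. For Ncor2 itself the change was 0.23, a call that ended in several fits with 1 library left out.

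The shNcor1 effect differed between the days for 123 genes, a number that moved with the library left out. The effect changed by 0.89 for Ndrg1 and -0.83 for Myh9, the latter on stepped values.

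The broad response to shNcor2 on day 5 (4042 genes) was weighed against 3 explanations. GC content as its whole cause is argued against by the correction, after which 3981 genes passed, 3728 of them in both fits. Replicate 2 stood apart from replicate 1 on the first principal component (-29 against -38.2), but one deviating library as the whole cause is argued against by the leave-one-out fits: 2838 genes passed without replicate 2 and 2778 without replicate 1. Lower levels of the 4 reprogramming factors (median log2 -0.56 on day 5, on stepped values that may reflect rank alone) may account for part of it. On day 9 their median was -0.05 and that of the TGF-beta and contractile list still 0.28. But Myc was still lower then (log2 -0.73), and Pou5f1 and Klf4 held 1 stepped value, which can hide a change. So for day 5 this explanation cannot be told apart from an effect of shNcor2 itself. With 1 shRNA label per target, loss of SMRT and other hairpin effects are not separated. Deviation of both libraries alike, and the authors' normalization, stay open.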

How the results depend on the processing

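No named gene's call or list call turned its direction under any alternative. Which direction held more genes did turn: with the GC correction there were 2138 higher and 1843 lower genes for shNcor2 on day 5, 1345 and 1257 for shNcor2 on day 9, 1445 and 1842 for shNcor1 against shNcor2 on day 5, 3470 and 3280, 3503 and 3283, and 3216 and 3079 for the days with shLuc, shNcor1 and shNcor2, and 1242 and 1452 for the change of the shNcor2 effect. Median-ratio scaling turned it for 5 of these 7 comparisons, as the days with shNcor1 and with shNcor2 kept theirs. The planned filters removed no gene and so test nothing. Counts stayed within 1.5 times under both scalings, both pseudocounts, the GC correction, the filter at 200 and without genes of mean 4000 or more, the last 3 chosen after seeing the data. The replicate number as a block changed no named gene or list call and gave 88 to 6879 genes per comparison, each within 1.5 times. With 1 library left out, the lone library of its group is assumed to vary like the others. The lowest and highest counts were 100 and 236 (shNcor1, day 5), 2778 and 2942 (shNcor2, day 5), 165 and 496 (shNcor1, day 9), 1172 and 1845 (shNcor2, day 9), 1948 and 2149 (shNcor1 against shNcor2, day 5), 949 and 1382 (the same, day 9), 5828 and 6004 (days, shLuc), 5870 and 6283 (days, shNcor1), 5264 and 5627 (days, shNcor2), 22 and 160 (change of the shNcor1 effect), and 1742 and 2217 (change of the shNcor2 effect). Each such fit has fewer residual degrees of freedom by construction.

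With only the libraries compared, the counts were 11 (shNcor1, day 5), 90 (shNcor1, day 9), 1501 (shNcor2, day 9), 532 (shNcor1 against shNcor2, day 9) and 18 (change of the shNcor1 effect), and Ncor1 on day 5 (log2 -0.51) had an adjusted p of 0.0731, with fewer residual degrees of freedom by construction. Without a trend in the variance, 576 genes passed for shNcor1 on day 9 and 30 for the change of its effect, and the cause was not tested. At an adjusted p under 0.01 the counts were 140 (shNcor1, day 5), 2487 (shNcor2, day 5), 187 (shNcor1, day 9), 1147 (shNcor2, day 9), 1789 and 734 (shNcor1 against shNcor2, days 5 and 9), 9 (change of the shNcor1 effect) and 1187 (change of the shNcor2 effect). At a size of at least 2-fold they were 9, 161, 18 and 70 for the knockdowns in the same order, 108 and 55 for shNcor1 against shNcor2, 737, 826 and 731 for the days with shLuc, shNcor1 and shNcor2, and 7 and 111 for the changes of effect. Neither corepressor fell that far under its own hairpin (Ncor1 -0.51 and -0.56, Ncor2 -0.88 and -0.65). At that size both knockdowns shared 3 higher and 2 lower genes on day 5 and 4 and 3 on day 9, and the days shared 0 and 0 for shNcor1 and 20 and 5 for shNcor2.

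Of 812 results for named genes with 1 library left out, 11 lost and 1 gained a call. Of 133 list calls, 131 were lost with an estimated correlation, 11 with fry, 3 with quantile normalization, 2 with median-ratio scaling and 1 with the GC correction, and 62 of 668 were lost with 1 library left out. No scaling moved the median of all genes by over 0.1. The depth is unknown, and steps above 4000 limit the highest genes.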

Other observations

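The tests of each knockdown's course were chosen only after the result was seen. Those of shared controls, GC content and hypoxia-inducible genes were written down before they were run. Values of part of the hypoxia-inducible genes had been seen by then. Besides the list calls in the report, 10 were made in the 4 comparisons with shLuc, and each ended with an estimated correlation and without at least 1 library. On day 5 with shNcor1, 0 of 20 G2/M genes were higher and 1 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.471 with an estimated correlation, 0.385 without shLuc replicate 1). Of epithelial genes, 1 of 22 was higher and 3 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.36 with an estimated correlation). With shNcor2 on day 5, 5 of 16 mesenchymal regulators were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0228, adjusted p = 0.251 with an estimated correlation, 0.0616 without shLuc replicate 1).

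On day 9 with shNcor1, 3 of 20 G2/M genes were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.000201, adjusted p = 0.351 with an estimated correlation). Of late pluripotency genes, 2 of 7 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.33 with an estimated correlation). Of mesenchymal regulators, 0 of 16 were higher and 2 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.33 with an estimated correlation, 0.196 without shNcor1 replicate 2). Of p53 and senescence genes, 1 of 19 was higher and 1 lower (7 and 1 adjusted over the list alone, camera up at adjusted p = 0.0143, adjusted p = 0.435 with an estimated correlation). Of DNA replication genes, 0 of 22 were higher and 1 lower, though camera called the list as higher (0 and 1 adjusted over the list alone, camera adjusted p = 0.0449, adjusted p = 0.651 with an estimated correlation). With shNcor2 on day 9, 3 of 7 late pluripotency genes were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.218 with an estimated correlation, 0.0798 without shNcor2 replicate 2). Of interferon response genes, 2 of 8 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.0336, adjusted p = 0.442 with an estimated correlation).

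In the NCoR and SMRT complex list, 1 of 14 measured genes passed with shNcor1 on day 5 and was lower, Ncor1 itself (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.969). With shNcor2 on day 5, 2 of its genes were higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.686). For oxidative phosphorylation, 0 of 21 genes were higher and 1 lower with shNcor1 on day 5 (0 and 1 adjusted over the list alone, camera adjusted p = 0.15), and 0 and 5 with shNcor2 (0 and 3 adjusted over the list alone, camera adjusted p = 0.342). For ER stress and ATF4 targets on day 9, 0 of 16 were higher and 1 lower with shNcor1 (2 and 3 adjusted over the list alone, camera adjusted p = 0.584), and 6 and 0 with shNcor2 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0914). Of markers of other cell types, the table held 13 keratinocyte, 7 primitive endoderm and 7 neural genes, but 2 endothelial genes, 1 each for macrophages, trophoblast and germ cells, and 3 myogenic genes. Of the neural genes, 0 were higher and 0 lower with shNcor1 on day 5 (1 and 0 adjusted over the list alone, camera adjusted p = 0.14) and on day 9 (0 and 0 adjusted over the list alone, camera adjusted p = 0.732). With shNcor2, 2 were higher and 0 lower on day 5 (2 and 0 adjusted over the list alone, camera adjusted p = 0.159), and 2 and 1 on day 9 (2 and 1 adjusted over the list alone, camera adjusted p = 0.342).

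On day 9, 7 of 17 early pluripotency genes were higher and 0 lower with shNcor1, and 7 higher and 1 lower with shNcor2 (medians 0.42 and 0.22, 10 and 0, and 7 and 1, adjusted over the list alone), list calls that ended with an estimated correlation (adjusted p = 0.115 and 0.14). An off value in 1 shared shLuc library is argued against, since against either control library alone the medians ran from 0.22 to 0.46 with the controls 0.03 apart, while both controls deviating alike stays open. After the GC correction, with the limit given above, the medians were 0.4 and 0.24. That cells were further along the day 5 to day 9 course may hold for shNcor1. Its day 9 effect correlated with the other knockdown's course (r = 0.24 across genes, not independent replicates, 0.2 to 0.28 leaving out 1 library). For shNcor2 the same r was -0.02 (-0.05 to 0.01), no net advance. Its lists moved with the course (keratinocyte median 0.49) and against it (contractile 0.28). A masked advance there and an effect of each corepressor itself stay open.

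A further hypothesis was that hypoxia-inducible genes fell as a set with shNcor2 on day 5, since Slc16a3, Pdk1 and Bnip3 were among the largest falls. Of 34 such genes written down before the test, 31 were measured (median log2 -0.42, -0.2 on day 9 and 0.67 for day 9 against day 5 in shLuc). Of the 19 whose values had not been looked at, 10 were lower and 2 higher past the threshold (median log2 -0.14, camera p = 0.00553, p = 0.0527 with an estimated correlation). The unseen genes thus leave it open whether the set fell, and the seen ones cannot decide it, having led to the hypothesis. After the GC correction, with the same limits, the median of the whole list was -0.4.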
